A study of Mus musculus with 2 samples.

How the data were processed

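Total RNA from whole ovaries of wild type CD-1 mice was extracted with Trizol, cleaned on columns and, from 100 ng, turned into biotin-labelled RNA for Affymetrix Mouse Genome 430 2.0 arrays, per the labels' protocols. There were 2 samples, 1 from vehicle-treated and 1 from ulipristal-treated mice. The labels do not say how many mice each sample came from. A sample's group was taken from its treatment label.

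The deposited values are probe set intensities on a linear scale, in arbitrary units. The submitters' processing notes name MAS5 and Affymetrix Expression Console version 1, without saying which step each did. MAS5 combines the probes of a probe set into 1 signal. The values bear out a global scaling, since the mean without the lowest and highest 2% of values is 150.001 on both arrays. Such scaling makes the arrays equal on average, so a shift shared by most genes would not be visible. Detection calls were not used here, and the genome build is not given in the sources used here, so no coordinates are printed. For arrays, their number limits the precision, and it is 1 per group.

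Of 45101 probe sets, 64 were controls, 34945 named 1 gene, 932 several and 9160 none in the platform annotation used. Only probe sets with 1 gene gave gene values. Their gene identifiers were found in the RefSeq gene table (assembly GRCm38.p6, used for names only) for 34741 probe sets, and 0 symbols differed.

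Signals below 7.17, the 25th percentile of both arrays' non-control values, were set to that floor, and log2 was taken. The ratio is log2 of ulipristal minus log2 of vehicle. Where a signal was at the floor, the fold is a lower bound. A gene was represented by its probe set with the highest mean log2 signal. It counted as measured where that mean was at or above the median of all non-control probe sets, a signal of 30.8. This left 22519 probe sets and 11364 genes. A gene was called higher or lower at 2-fold or more. The log2 signals of both arrays correlated across measured probe sets with Pearson's r of 0.962, where probe sets are not independent replicates. The median log2 ratio of measured probe sets was 0.06.

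The 35 gene lists, the thresholds and the rule for named genes were fixed before the data were examined. Each list's median ratio was placed among 10000 random lists of equal size, drawn from measured genes of the same decile of mean signal (seed 1). A median outside the 2.5th to 97.5th percentile is described as outside the random range. Genes are not replicates, so this percentile describes these arrays and is not a p-value. Lists share genes and are not independent. The text names 20 genes fixed in advance, the 12 highest and 12 lowest ratios among genes whose measured probe sets agree in direction and whose symbols are not placeholders, and up to 4 members of each list with the largest ratios (2 where no member reached 2-fold). A gene with 1 measured probe set meets the condition on direction without a comparison. A gene named outside the rule for named genes is said to have been chosen after its values were seen.

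The steps were tested on a simulated pair of arrays with the real signals and noise set per decile of signal. Of genes simulated with a 3-fold change, 48 of 50 higher and 46 of 50 lower were recovered. At 6-fold these were 49 of 50 and 49 of 50. Of 11221 unchanged genes 2.20% reached 2-fold. This is not a false-call rate for the real arrays, since the noise came from the ratios between them, any treatment difference included. The shift of ratios with signal was not simulated. Of 200 unchanged lists of 15 genes, 10 lay outside the random range, and all 50 lists shifted by -1 on the log2 scale lay below it. These lists only check the steps. Unchanged lists were drawn at random with independent noise, so about this share outside was set by construction, and the shift was large. Lists of genes that vary together were not simulated.

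Alternatives were median centring, quantile normalization, lowess centring against signal (fraction 0.3), no floor, a floor at the 50th percentile, no filter, a filter at the 75th percentile, a pseudocount of 50, the median over a gene's probe sets, leaving out probe sets that can bind several transcripts (IDs with s or x), and 1.5-fold and 3-fold in place of 2-fold. The pseudocount took the place of the floor, so that setting changed both. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.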

Results

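Ovarian messenger RNA was profiled in immature CD-1 mice, 24 to 28 days old, that had been primed with 5 IU of pregnant mare serum gonadotropin (PMSG) and given 5 IU of human chorionic gonadotropin (hCG) 48 h later. PMSG grows a cohort of preovulatory follicles, and hCG acts on the luteinizing hormone (LH) receptor to start ovulation. The mice received oil vehicle or ulipristal acetate, a synthetic ligand that modulates the progesterone receptor and is used as an emergency contraceptive, 2 h after hCG, and ovaries were taken at 11 h (the labels do not say after which injection). The design compares the ovary with and without the drug during the ovulatory response. There were 2 arrays, 1 per treatment, each holding MAS5 signals for 45101 probe sets, and 11364 of 18193 named genes passed the filter on low signal. With 1 array per treatment there is no spread between animals or arrays, so no test between the treatments, standard deviation between samples or p-value is given. Every difference is between these 2 samples, each ratio is ulipristal over vehicle, and signals are in arbitrary units with a trimmed mean of 150.001 on both arrays.

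The message of the progesterone receptor itself, Pgr, was higher after ulipristal. Its signal was 49.2 on the vehicle array and 350.6 on the ulipristal array, a 7.13-fold difference. Only 1 of the 3 Pgr probe sets was bright enough to be measured. The others read 1.28 and 0.75 on the vehicle array and 8.63 and 3.33 on the ulipristal array, at or near the floor of 7.17. The ratio of the measured probe set was 2.83 on the log2 scale and 2.01 when 50 was added to every signal. Oviduct markers also had a higher median on the ulipristal array. Whether a difference in tissue content between the samples contributed to the Pgr value was not tested.

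Genes known to depend on the progesterone receptor in the ovulating follicle had a lower median after ulipristal, with 18 of 20 measured members below 0. Edn2, the vasoconstrictor peptide endothelin 2, had a signal of 3363 with vehicle and 134 with ulipristal, a 25.1-fold difference. Il6, the cytokine interleukin 6, was 21.2-fold lower, with signals of 713 and 33.7. Snap25, a membrane fusion protein of regulated secretion, was at least 20.1-fold lower, from 144 to below the floor. Adamts1, a protease that cleaves versican, was 6.94-fold lower, with signals of 6495 and 936. Prkg2, a cyclic GMP-dependent kinase, was 6.51-fold lower on its brightest probe set. Its 3 probe sets gave log2 ratios of -2.70, -2.52 and -2.10. Zbtb16, a zinc finger transcription factor, was 4.43-fold lower, with log2 ratios from -2.49 to -0.88 over 3 probe sets. Of these 20 genes, 10 were at least 2-fold lower, 0 were at least 2-fold higher and 10 lay between. The list's median log2 ratio was -1.09, below all 10000 random lists of equal size and matched signal, whose middle 95% ran from -0.17 to 0.16. The members above 0 were Arnt (1.61-fold higher) and Slc38a3 (1.36-fold higher), both chosen after their values were seen. Among the members that did not reach 2-fold were Pparg, a nuclear receptor (1.54-fold lower, 267 against 173), the hypoxia factors Hif1a (1.51-fold lower) and Epas1 (1.39-fold lower), each with a dimmer probe set past 2-fold (log2 ratios of -1.08 and -1.16), and Ctsl, the lysosomal protease cathepsin L (1.53-fold lower, 10282 against 6708). Control features were also brighter on the vehicle array, poly-A spikes by 1.49-fold and 18S ribosomal RNA by 2.41-fold, whereas housekeeping genes had a median log2 ratio of -0.15.

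**Figure D1:**
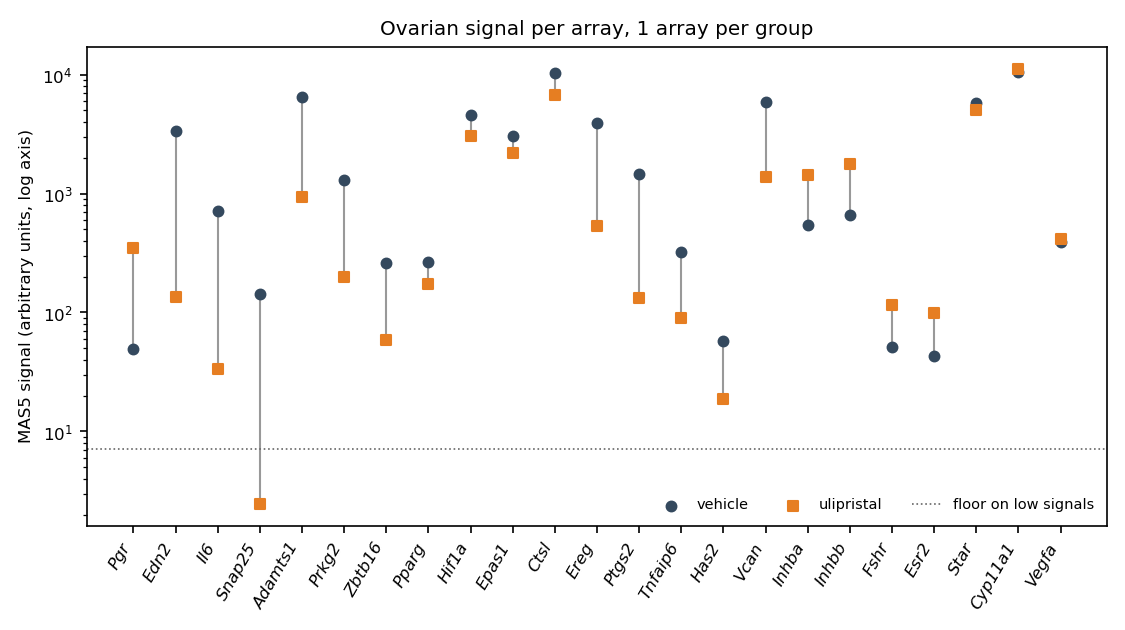
MAS5 signal (arbitrary units, log axis) of 23 genes on the vehicle array (circles) and the ulipristal array (squares), 1 array per treatment and no error bars. Edn2 read 3363 with vehicle and 134 with ulipristal, Pgr read 49.2 and 350.6, and the pairs for Star, Cyp11a1 and Vegfa nearly overlap.

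Genes of cumulus expansion, the swelling of the matrix around the oocyte before its release, had a lower median, with 11 of 12 members below 0. Of these members, 7 were at least 2-fold lower and 0 at least 2-fold higher, and the median log2 ratio was -1.70 against a random range of -0.16 to 0.33. Ptgs2, the inducible cyclooxygenase, was 11.1-fold lower, with signals of 1467 and 132. Vcan, the matrix proteoglycan versican, was 4.28-fold lower, and its 4 measured probe sets agreed in direction. Tnfaip6, a hyaluronan-binding protein, was 3.58-fold lower. Has2, a hyaluronan synthase, was 3.08-fold lower at low signals of 58.0 and 18.8, and was less than 2-fold lower under 2 of 9 alternative settings. The list shared Adamts1 and Ereg with the progesterone receptor list. In the prostaglandin pathway, Ptgs2 was the only 1 of 13 measured members that differed by 2-fold or more. Slco2a1, a prostaglandin transporter, had signals of 836 and 431, and its 4 measured probe sets gave log2 ratios from -1.01 to 0.03. The median of the prostaglandin list, -0.09, lay inside its random range.

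Epidermal growth factor-like ligands and feedback regulators of the ERK pathway had a lower median, with 10 members below 0 and 6 above. Of 16 measured members, 8 were at least 2-fold lower and 1 at least 2-fold higher, with a median log2 ratio of -0.85 and a random range of -0.11 to 0.32. The higher member was the receptor Erbb3 (2.03-fold), and the ligand Hbegf (64.9 against 95.2) and the feedback gene Spry1 (153 against 187) were also above 0. These 3 genes were chosen after their values were seen. Ereg, the ligand epiregulin, was 7.26-fold lower (3881 against 534) and Btc, betacellulin, was 3.44-fold lower at low signals of 78.7 and 22.9. The phosphatases Dusp5 and Dusp4, which act on ERK-family kinases, were 4.47-fold and 3.24-fold lower. Among cytokines and adhesion molecules, 6 of 14 measured members were at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.56 and a random range of -0.13 to 0.34. Besides Il6 these included Il11, a cytokine of the same family (7.46-fold), Socs3, a feedback inhibitor of cytokine signalling (4.45-fold, 3 probe sets), and Selp, the adhesion molecule P-selectin (2.60-fold). The higher member was the chemokine Cxcl10 (2.44-fold). The other 14 members of that list were too dim to be measured.

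Immediate early genes, which respond quickly to hormones and to handling alike, had a lower median, with log2 ratios below 0 for all 19 measured members. Of these, 11 were at least 2-fold lower, and the median log2 ratio was -1.26 against a random range of -0.13 to 0.22. Egr3 was 8.90-fold lower (492 against 55.3), Egr2 was 5.83-fold lower, and Ccn1, a secreted matrix protein, was 5.05-fold lower with 4 probe sets in the same direction. Among transcription regulators induced by LH, 6 of 18 were at least 2-fold lower and 1, Pgr, was higher, with a median of -0.67 and a random range of -0.17 to 0.17. The lower members included Fosl1 (4.87-fold, at signals of 86.4 and 17.7), Nr4a2 (3.14-fold) and Fos (3.13-fold), and 5 measured genes stood in both lists. The 4 measured probe sets of Nr4a2 gave log2 ratios from -1.65 to -0.46. Genes that respond to the glucocorticoid or progesterone receptor had 5 of 18 members at least 2-fold lower and 0 higher, with a median of -0.64 and a random range of -0.19 to 0.15. Errfi1, a feedback inhibitor of the epidermal growth factor receptor, was 6.38-fold lower (6713 against 1053). Mt2, a metallothionein, and Cebpd, a C/EBP-family transcription factor, were 3.53-fold and 3.05-fold lower. Zbtb16 and Mt1, the latter 2.73-fold lower and chosen after its values were seen, were the others. Of these lower members, Mt1, Mt2 and Zbtb16 were already counted in the progesterone receptor list. Heat shock and endoplasmic reticulum stress genes differed by less than 2-fold in all 16 cases. Their median of -0.25 lay below the random range of -0.20 to 0.16, and Hspa5, a chaperone of the endoplasmic reticulum, had signals of 9533 and 6371.

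Proteases and their inhibitors had 5 of 18 measured members at least 2-fold lower and 1 higher, with a median log2 ratio of -0.46 and a random range of -0.18 to 0.18. After Adamts1 came Adamts4, a related protease (3.79-fold lower), and Mmp19, a matrix metalloproteinase (2.09-fold lower at low signals). Adamts9 (2.03-fold) and Plau, the urokinase gene (2.07-fold), both chosen after their values were seen, were the remaining lower members. Serpina5, a serine protease inhibitor, was 2.33-fold higher. With the filter on signal raised to the 75th percentile, the median of this list moved inside its random range. Components of the matrix differed by less than 2-fold in all 20 cases, and their median of 0.12 lay just above the random range of -0.23 to 0.05. Col6a1 and Lum, a collagen chain and a small proteoglycan of stroma, had the highest ratios, with 1.78-fold and 1.68-fold. Genes of endothelin signalling and vascular tone went both ways: their median was 0.09, inside the random range, and their mean was -0.27. Edn2 and Prkg2 were the 2 lower members, and Npr2, the receptor for C-type natriuretic peptide, was 2.32-fold higher (264 against 611), as was Agtr2, an angiotensin receptor, by 2.01-fold at low signals. Angiogenic factors differed by less than 2-fold in all 14 cases, with a median of -0.0035. Vegfa, the main vascular growth factor, read 389 with vehicle and 415 with ulipristal. Of 25 measured hypoxia-response genes, 3 were at least 2-fold lower and 1 higher, and the median of -0.03 lay inside the random range. The lower members were Ndrg1 (2.47-fold), Egln3, an oxygen-sensing hydroxylase (2.32-fold), and Slc2a1, a glucose transporter (2.03-fold), whereas Pfkl, a glycolytic enzyme, was 2.41-fold higher. The 2 measured probe sets of Pfkl gave log2 ratios of 1.27 and 0.46, and the 3 of Slc2a1 ranged from -1.02 to -0.33. Pfkl reached 2-fold under 7 of 9 alternative settings, Egln3 under 8 of 9 and Slc2a1 under 8 of 10.

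Granulosa cell genes listed in advance as driven by follicle-stimulating hormone (FSH) had a higher median after ulipristal, with 11 members above 0 and 4 below. Of 15 measured members, 5 were at least 2-fold higher and 0 at least 2-fold lower, with a median log2 ratio of 0.34 and a random range of -0.22 to 0.16. The members below 0 included Amh (1.62-fold lower at signals of 48.7 and 30.1) and Ccnd2 (1.34-fold lower), both chosen after their values were seen. Inhbb and Inhba, the beta subunits of inhibin and activin, were 2.72-fold (656 against 1781) and 2.62-fold higher (544 against 1426). Gata4, a transcription factor of gonadal somatic cells, was 2.55-fold higher. Esr2, estrogen receptor beta, and Fshr, the FSH receptor, were 2.28-fold and 2.26-fold higher at signals from 43.1 to 115.8. With 50 added to every signal, the log2 ratios of Esr2 and Fshr were 0.67 and 0.71. The medians of theca, surface epithelium, oviduct, adipose and endothelial markers also lay above their random ranges.

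Steroid synthesis genes stayed inside their random range as a group. Of 14 measured members, 1 was at least 2-fold higher and 1 lower, with a median of 0.04, a mean of -0.06 and a random range of -0.23 to 0.13. Star, which delivers cholesterol to the mitochondrion, read 5733 with vehicle and 5016 with ulipristal, and its 3 probe sets gave log2 ratios of -0.19, 0.19 and -0.17. Cyp11a1, which makes pregnenolone from cholesterol, read 10451 and 11177. The lower member was Akr1c18, the enzyme that inactivates progesterone (3.03-fold, 1077 against 355), and the higher was Nr0b1, an orphan nuclear receptor (2.06-fold, 31.2 against 64.4). Cholesterol synthesis genes differed by less than 2-fold in all 20 cases, with a median of -0.15 inside the random range. Hsd17b7, which acts in both cholesterol and estradiol synthesis, had signals of 5753 and 3182. Luteinization genes had 3 of 14 members at least 2-fold lower and 1 higher, with a median of -0.11 inside the random range. Cdkn1a, a cell cycle inhibitor, was 3.53-fold lower and Btg2, an antiproliferative gene, 2.58-fold lower. Akr1c18 was the third lower member and Inhba, which is also in the list of FSH-driven genes, the higher one. Btg2 is also in the list of immediate early genes. Cell cycle genes differed by less than 2-fold in all 27 cases, with a median of 0.13, also inside. The probe annotation named no single-gene probe set for Areg, Cyp19a1 or Lhcgr, which are not analysed here.

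**Figure D2:**
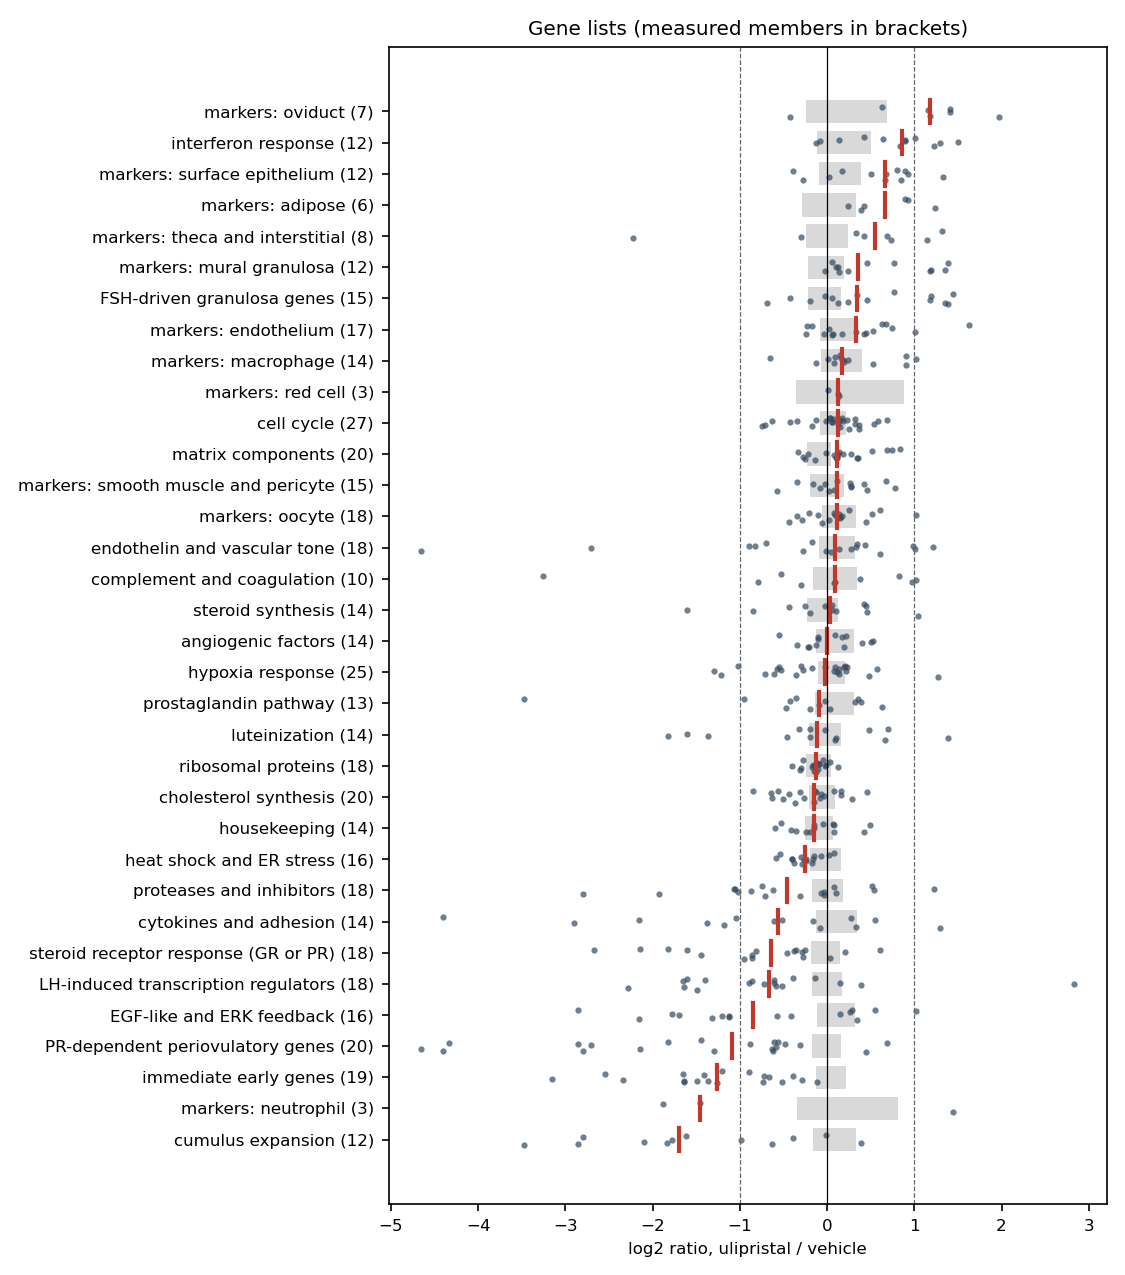
Log2 ratio of each measured member (points) of the 34 lists with at least 3 measured genes, ordered by median (red bars), with the middle 95% of medians of 10000 random lists (grey boxes) and 2-fold (dashed lines). The cumulus list has the lowest median, -1.70, and the oviduct markers the highest, 1.18.

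Markers of other cell types were compared because whole ovaries were used. Oviduct markers had a higher median, with 5 of 7 measured members at least 2-fold higher and 0 lower, and a median log2 ratio of 1.18 against a random range of -0.24 to 0.69. Foxj1, the transcription factor of motile cilia, was 3.93-fold higher at low signals of 19.1 and 75.1. The cilium genes Ccdc39 and Tmem212 were 2.66-fold and 2.65-fold higher and the secreted protein gene Wfdc2 2.26-fold. The fifth was Tppp3, chosen after its values were seen (2.23-fold). Foxj1, Tmem212 and Wfdc2 each reached 2-fold under 8 of 9 alternative settings, and Ccdc39 under 7 of 8. Surface epithelium markers had a median of 0.67 and a random range of -0.09 to 0.39. Among them Epcam, an epithelial adhesion molecule, had signals of 107 and 268, a log2 ratio of 1.32, and Krt18, a keratin, was 1.91-fold higher. Adipose markers had a median of 0.66, with Cidec 2.36-fold higher and Adipoq, the hormone adiponectin, at 195 and 370. Theca and interstitial markers had a median of 0.55 over 8 members, yet Hhip, a hedgehog-binding protein, was 4.67-fold lower with 3 probe sets in the same direction. Tcf21 and Fabp3 from this list were 2.22-fold and 2.49-fold higher. Mural granulosa markers had a median of 0.35 with 4 of 12 at least 2-fold higher, but 10 of these 12 are also in the list of FSH-driven genes. Endothelial markers had a median of 0.33, just above their random range of -0.09 to 0.31. Tie1 and Pecam1 were the members at least 2-fold higher (3.10-fold and 2.01-fold). The median lay inside its random range under 3 of 10 alternative settings. Medians lay inside the random range for markers of oocytes (0.11, 18 measured), macrophages (0.17, 14 measured), smooth muscle and pericytes (0.12, 15 measured) and red cells (0.13, 3 measured). Kit, a receptor of oocytes and stroma, and C1qc, a complement gene of macrophages, were each 2.03-fold higher. Several ratios close to 2-fold did not reach it under 4 or 5 of the alternative settings, those of Kit, C1qc, Pecam1, Nr0b1, Agtr2 and the interferon-response gene Oasl2. The neutrophil markers S100a9 and S100a8 were 3.69-fold and 2.75-fold lower, and the third measured member, Ltf, was 2.72-fold higher. The median of these 3, -1.46, lay below the random range, but without s and x probe sets, S100a8 among them, it was -0.22 over 2 genes and inside. Of the lymphocyte markers only Gzmb was measured, with signals of 47.6 and 32.9.

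Across all measured genes, 380 (3.34%) were at least 2-fold higher and 177 (1.56%) at least 2-fold lower, so that 68.2% of those past 2-fold were higher. That share was 57.3% after quantile normalization and 56.7% after lowess centring. It turned to a minority, 36.5% with the filter on signal at the 75th percentile and 35.5% with 50 added to every signal. The 12 lowest and 12 highest ratios were taken among genes whose measured probe sets did not differ in direction. Of the genes so chosen, only Ankrd1, Zfp949 and Plet1 had more than 1 measured probe set. For the others there was no agreement to check. The 12 lowest ratios were led by Ankrd1, an ankyrin repeat protein, which was at least 35.1-fold lower. It went from 251 to below the floor, with both probe sets in the same direction. After Edn2, Il6, Snap25 and Ptgs2 came Has1, a hyaluronan synthase (9.83-fold, 213 against 21.6), and F3, the coagulation starter tissue factor (9.53-fold, 1664 against 174). They were followed by Egr3, Il11, Ereg, Epgn, an epidermal growth factor-like ligand (7.03-fold), and Adamts1. The 12 highest ratios were mostly of dim genes. They were led by Padi1, a peptidylarginine deiminase (8.16-fold, 14.7 against 120), and Pgr. Then came Napsa (6.40-fold), Cyp26a1, which breaks down retinoic acid (5.41-fold), Rbm24 (4.91-fold), Zfp949 (4.70-fold), Trim5 (4.61-fold), Ecm2 (4.43-fold), Plet1 (4.41-fold, 244 against 1076), Fads2b (4.41-fold), Trim34a (4.39-fold) and Rtn1 (4.37-fold). Trim5 and Trim34a belong to a family of close paralogs, so their values are less certain. With 50 added to every signal, which damps dim genes, the log2 ratios of these 12 lay between 0.85 (Ecm2) and 2.17 (Zfp949, for which another probe set was then the brightest). Those of the 12 lowest lay between -4.22 (Edn2) and -1.22 (Il11), and that of Ankrd1 was -2.45.

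The balance of higher and lower genes depended on signal. In the dimmest quartile of measured genes 273 were at least 2-fold higher and 56 lower, and in the brightest 18 were higher and 58 lower. The median log2 ratio was 0.25 in the dimmest quartile and -0.07 in the brightest. Probe sets of the same gene are the sole repeat measurement on these arrays, and their ratios differed with a standard deviation of 0.37 on the log2 scale (4955 genes). Among genes past 2-fold with several measured probe sets, 70 of 73 lower genes and 53 of 65 higher genes had every probe set in the same direction. Control features showed how far the arrays differed: hybridisation spikes were 1.19-fold brighter on the vehicle array, poly-A spikes 1.49-fold and 18S ribosomal RNA 2.41-fold. The ratio of 3' to 5' signal, a sign of RNA or labelling quality, was 2.40 for Actb on the vehicle array and 1.87 on the ulipristal array. For Gapdh it was 1.20 and 0.866. Housekeeping and ribosomal protein genes differed by less than 2-fold in all 14 and 18 cases, with medians of -0.15 and -0.12 inside their random ranges. Of the 35 lists, 10 had medians below and 9 above the middle 95% of random lists. By chance 1.75 would lie outside if the members of each list varied independently, as in the random lists. Genes of a list may vary together, so the comparison with 1.75 is not a measure of chance here.

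**Figure D3:**
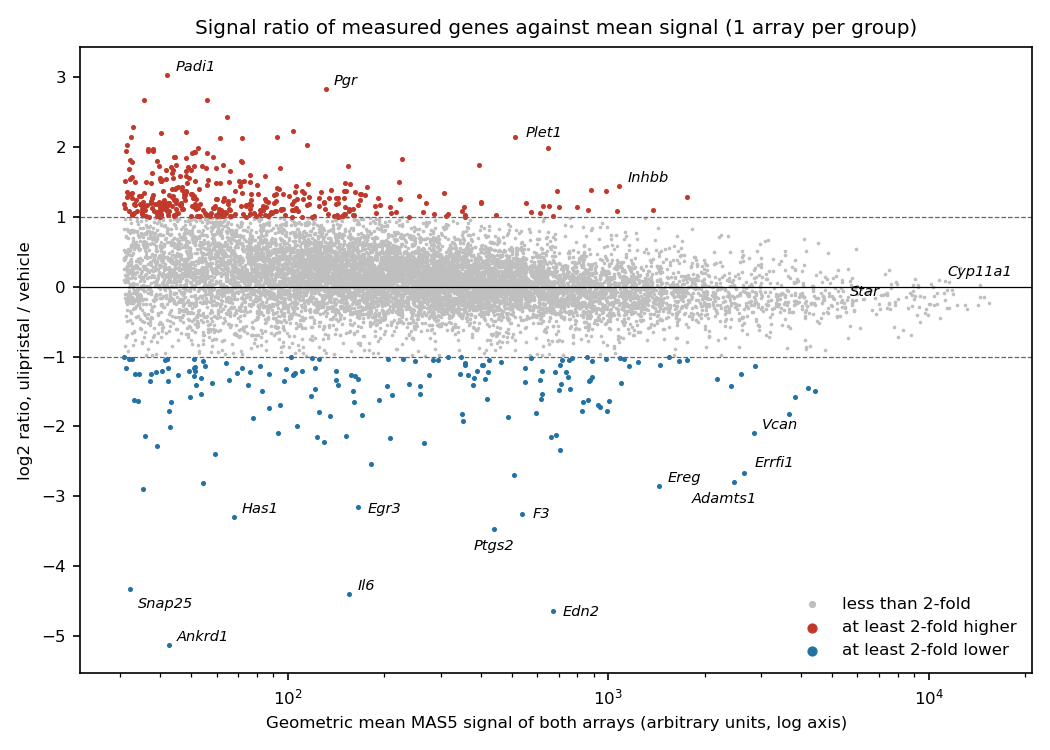
Log2 ratio of ulipristal over vehicle (vertical axis) against the geometric mean MAS5 signal of both arrays (log axis) for 11364 measured genes, with 1 array per treatment. The 380 higher genes gather at low signal, whereas lower genes are spread over the signal range. Edn2, Ereg and Adamts1 are among the brighter of the lower genes.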

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

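The tests of a scale difference, of the granulosa share and of handling as a source of the immediate early genes were chosen only after the result was seen.

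Outside the named genes, 67 of 3052 measured probe sets that name no gene or several were at least 2-fold higher on the ulipristal array than on the vehicle array, and 105 were at least 2-fold lower. The gene comparison did not use these data. The higher share, 2.20%, lay below the 3.34% of named genes, whereas the lower share was 3.44% against 1.56% of named genes. The largest were the probe sets 1452426_x_at (24.7 against 235) and 1456319_at (36.2 against 143) upward, and 1455869_at and 1421134_at downward, which went from 162 and 158 to below the floor.

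The medians of oviduct and epithelial markers were higher after ulipristal; if this sample held more adjacent oviduct or surface tissue, motile cilium genes outside the marker list should be higher too. Such a list of 49 genes was drawn up before their values were looked at. Of these, 44 had a named probe set and only 15 were bright enough to be measured. The 15 had a median log2 ratio of 1.15, above all random lists (range -0.05 to 0.57), and all 15 were above 0. The filter uses the mean of both arrays, so a dim gene that is high on 1 array passes more easily. The count above 0 thus does not describe the whole list. The lowess-centred median was 1.02 and stayed above all random lists. Those lists are matched on signal, so a drift shared by dim probe sets was already in their range. The measured cilium genes thus lay above genes of like signal, and the centring adds little to this. Ovgp1, the abundant oviduct glycoprotein, chosen after its values were seen, was bright on both arrays (3641 and 5642), with a log2 ratio of 0.63, below the median of the cilium genes. Unevenly trimmed tissue may contribute, and an effect of the drug on epithelium was not tested and stays open.

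The medians of receptor-dependent and immediate early genes were lower after ulipristal. The lowess-centred median of the receptor list was -1.06 and stayed below all random lists. As a test of a scale difference between the arrays this could hardly have come out otherwise. Median log2 ratios ran only from 0.25 in the dimmest quartile of measured genes to -0.07 in the brightest. Random lists matched on signal already carry a shift shared by genes of like signal, so the receptor list differed from such genes. The median of mural granulosa markers was 0.35 and above its random range. It cannot decide on a smaller share of granulosa cells, because 10 of these 12 genes are also in the FSH-driven list. That list itself had a higher median, so a change in expression and a change in cell share cannot be told apart. Handling before RNA was fixed stays open for the receptor list: leaving out members shared with the immediate early and ERK lists removed 1 of 20 genes, too few to decide, and the median of the other 19 was -0.89. For the immediate early genes handling and the drug cannot be told apart either, because heat shock genes also had a lower median (-0.25) and each treatment is 1 sample.

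More genes were at least 2-fold higher (380) than lower (177). Noise or drift of dim probe sets is a candidate explanation: among the brighter 5682 measured genes there were 35 higher and 87 lower, a ratio of 0.40, and probe sets of a gene agreed in direction for 81.5% of higher and 95.9% of lower genes. Added oviduct tissue would also raise dim genes, and the share of the excess that it makes up was not tested.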

How the results depend on the processing

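Of 338 list medians recomputed under the alternatives, 336 moved by less than 1.5-fold, and 0 of the medians outside their random range changed sign. The exceptions were the cumulus list, at -0.83 with a pseudocount of 50 and still below all random lists, and the neutrophil markers, at -0.22 with 2 genes left once s and x probe sets were left out. Of 1360 values of single genes 53 moved by more than that, and 0 of those past 2-fold changed sign. The side of the random range changed under at least 1 setting for proteases, interferon, endothelial and neutrophil lists, which came inside, and for cholesterol, hypoxia, prostaglandin and smooth muscle lists, which moved outside. Pgr moved to 2.01 with the pseudocount and was not measured under the filter at the 75th percentile.

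The counts of higher and lower genes (380 and 177) depended on the settings. They were 1025 and 460 without a filter, 58 and 101 with the filter at the 75th percentile, 54 and 98 with the pseudocount, 1403 and 520 at 1.5-fold, and 60 and 57 at 3-fold. The higher share of genes past the threshold, 68.2%, was 57.3% under quantile normalization, 56.7% under lowess centring, 36.5% with the filter at the 75th percentile, 35.5% with the pseudocount and 51.3% at 3-fold. The share of these genes whose probe sets had the same sign, 89.1%, was 38.1% without a filter, 74.96% at 1.5-fold and 100% with the median over probe sets, which selects for agreement. Without a filter, probe sets at the floor on both arrays enter with a ratio of 0, which was counted as a differing sign. Removing the floor left the counts at 380 and 176. No replicate could be left out. No paired analysis was possible because each treatment has 1 array.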

Other observations

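The test of a general block and the list of epithelial junction genes were chosen only after the result was seen. Interferon-response genes had a higher median after ulipristal, with 10 members above 0 and 2 below. Of 12 measured members, 4 were at least 2-fold higher and 0 lower, with a median log2 ratio of 0.86 against a random range of -0.11 to 0.50. Oas2, a sensor of double-stranded RNA, was 2.83-fold higher (19.9 against 56.3), the chemokine Cxcl10 2.44-fold, Ifit2 2.34-fold and Oasl2 2.00-fold, the last of which was below 2-fold under 4 of 9 alternative settings. Oas2 reached 2-fold under 7 of 9 of these settings, and Cxcl10 and Ifit2 each under 8 of 9. With the filter at the 75th percentile the median came inside the random range. Complement and coagulation genes went both ways, with a median of 0.09 and a mean of -0.15 over 10 members, F3 being 9.53-fold lower and the complement gene C1qc 2.03-fold higher (97.7 against 198). The related genes C1qa (242 against 256) and C1qb (162 against 173), chosen after their values were seen, differed little. Epithelial junction genes had a median of 0.79 over 9 measured members of 16 listed, and 4 were at least 2-fold higher.

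The lists fixed in advance differed in direction within the ovulatory response. Medians of cumulus, ERK and receptor-dependent genes lay below their random ranges, that of steroid synthesis genes inside, and that of FSH-driven genes above. A hypothesis, formed and tested on the same data, is a general block of the response to hCG. The median of steroid synthesis genes lay 0.70 above that of LH-induced regulators on the log2 scale. This does not decide the question, because the steroid list mixes genes that rise and genes that fall after the LH signal, and its members went both ways (8 above 0 and 6 below, from -1.60 to 1.04). The hypothesis stays open.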
